A study of Mus musculus with 6 samples.

How the data were processed

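The measurements are gene expression microarrays of 6 samples from adult C57/BL6 mice, 3 of carotid body and 3 of adrenal medulla. The carotid body is a chemoreceptor organ at the fork of the carotid artery that responds to low blood oxygen; the adrenal medulla is the inner part of the adrenal gland, whose chromaffin cells release adrenaline and noradrenaline. Per the labels, the animals were untreated, and every sample was a pool: 18 carotid bodies or, for the adrenal samples, 10 medullas, taken from 10 mice. Collection took 2 days, tissue was kept in RNAlater, RNA was isolated with a column kit for small amounts, and labelled RNA was made with a 3' in vitro transcription kit, per the labels' protocols. The series states that samples with the same group number came from the same cohort of animals, so the 3 cohort numbers pair a carotid body sample with an adrenal medulla sample.

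The deposited table holds 1 log2 value per probe set and array. The authors used Affymetrix Expression Console, per the submitters' processing notes; its version and the algorithm of summarisation and normalization are not given in the sources used here. That the deposited values are log2 intensities was read from the values themselves, which lie between 2.70 and 14.97 on every array. The arrays had similar quartiles, and no further normalization was applied; whether one between arrays had been applied before deposit was not tested. Medians of the non-control probe sets were 5.32, 5.30 and 5.25 for carotid body and 5.18, 5.16 and 5.18 for adrenal medulla. No detection calls came with the values, so a dim probe set cannot be told from an unexpressed gene, and differences near the floor of the scale are compressed. The number of arrays limits the precision. The 3' minus 5' log2 difference of the Gapdh control probe sets, which grows with RNA degradation or short labelled RNA, was 1.45, 1.04 and 0.59 in carotid body and 0.51, 0.13 and 0.61 in adrenal medulla.

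Of 45101 probe sets, 64 manufacturer controls were left out and 45037 were tested. Names came from the platform annotation of 2016: 34945 probe sets had 1 gene symbol, 932 had several and were left unnamed, and 9160 had none. Gene IDs of 34741 of the 1-symbol probe sets were found in a RefSeq table of GRCm38.p6, which changed 0 symbols. That table was used for names only. Each of 18193 genes was represented by its brightest probe set over the 6 arrays; 9010 genes had several probe sets, and 15 of these had probe sets called in opposite directions.

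The comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on log2 values, 2 groups, no block). P-values were two-sided and adjusted by Benjamini-Hochberg over all 45037 probe sets. A probe set or gene was called at an adjusted p under 0.05 and a difference of at least 2-fold. Differences are carotid body minus adrenal medulla, so positive values are higher in carotid body. Gene lists, 30 in all, were tested with limma's camera at a preset correlation of 0.01, adjusted over the 30 lists, with an estimated correlation beside it; fry was also run. The 3 planning choices, which are the tests, the lists and the alternatives, were fixed before the data were examined. The 3 pools of a tissue come from 3 cohorts of animals, so the spread between arrays of a tissue holds both animal and technical variation.

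Genes named in the text follow a rule. In each direction it takes the 10 largest differences with an adjusted p under 0.05, the same direction in all 3 cohort pairs and a mean in the higher tissue at or above the 75th percentile. In each list it takes the 4 largest differences with an adjusted p under 0.05, or the 2 brightest members where none passed. It also takes a fixed set of catecholamine, oxygen-sensing and cell type genes whatever their result. Genes of that set for which no probe set carried the symbol alone, Kcnk9 and Adora2a among them, are not analysed here. Lists fixed by the start of the symbol also hold genes of another kind: the noncoding transcripts Kcnq1ot1, Kcnmb4os1 and Kcnmb4os2, the binding proteins Rgs7bp and Rgs9bp, and the pseudogene Olfr75-ps1, which were noticed after their values were seen and stay in the counts. Other genes that are named were chosen after their values were seen, and are said to be.

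Pairing by cohort was checked as the correlation, over probe sets, of deviations from the tissue means. Same-numbered samples gave 0.22, 0.08 and 0.16 for cohorts 1, 2 and 3. Unlike-numbered samples gave -0.21 to 0.10, a range that holds the value of cohort 2. The basis for the pairing is the statement on cohorts. Alternatives were the cohort number as a replicate block, quantile normalization, centring of each array on its median, removal of the dimmer probe sets, an intensity trend with robust variances, array weights, the mean of all probe sets of a gene, limma's treat against 1.5-fold, and leaving out each array and each cohort. A choice of pseudocount was planned for linear values and was not run because the values are log2. Leaving out carotid body arrays 1 and 3 together was added after seeing the data. The fit and the list test were tested on simulated data made from the real means and variances of 45037 probe sets, of which 200 were changed. Of those changed by a log2 of 1, 46.3% were recovered at an adjusted p under 0.05; the shares were 88.1% at 2 and 98.5% at 4. Among unchanged probe sets, 4 had an adjusted p under 0.05 and 0 were called. The simulated probe sets were independent and no array stood apart, so effects of correlation between genes or of such arrays were not covered. Far fewer probe sets differed than the 10.5% called in the data, which makes the Benjamini-Hochberg threshold stricter in the simulation. The shares recovered therefore need not hold for the data.

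Marker lists of fetal, mast cell, liver and Y-linked genes were written after the first look at the data, for the tests in the closing section. Genes whose values had been seen by then were left out of the fetal, mast cell and Hox tests.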

Results

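Expression was measured on 6 arrays, 3 of mouse carotid body and 3 of adrenal medulla, each a pool of organs from 10 adult mice. The comparison sets the organ that senses arterial oxygen against a related catecholamine-producing organ, stated to come from the same cohorts of animals. The X-linked transcript Xist was 8.84 to 10.96 in carotid body and 4.45 to 5.60 in adrenal medulla, as given in the closing section. A difference in sex between the pools is therefore not excluded for any result below. Arrays of the same tissue correlated at 0.978 to 0.985 in carotid body and at 0.991 to 0.995 in adrenal medulla, and arrays of different tissues at 0.938 to 0.951. The first principal component held 74.0% of the variance and separated the tissues. The second held 11.9% and lay between carotid body array 1, at -51.8, and carotid body array 3, at 51.8.

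Carotid body had more RNA of matrix, vessel wall and glial genes and of the olfactory receptor Olfr78. The adrenal medulla pools had more RNA of several catecholamine synthesis genes and of steroid synthesis genes, which are genes of cortex cells. As whole lists, of these the matrix genes alone were also called with an estimated correlation between genes (adjusted p = 0.0297). At 2-fold and an adjusted p under 0.05 (limma), 1075 of 18193 genes were higher in carotid body and 1107 were higher in adrenal medulla. Differences over 16-fold were found for 45 genes higher in carotid body and 37 higher in adrenal medulla. Over probe sets, 2680 were higher in carotid body and 2064 in adrenal medulla, 10.5% of those tested. Of the called probe sets, 56.5% were higher in carotid body; with each array centred on its median, which moved the median difference of all probe sets by -0.11 (log2), this share was 46.0%. Without cohort 2, 1626 and 952 probe sets and 807 and 532 genes were called; without cohort 1 the genes numbered 1125 and 1219, and without cohort 3 1033 and 1180.

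**Figure D1:**
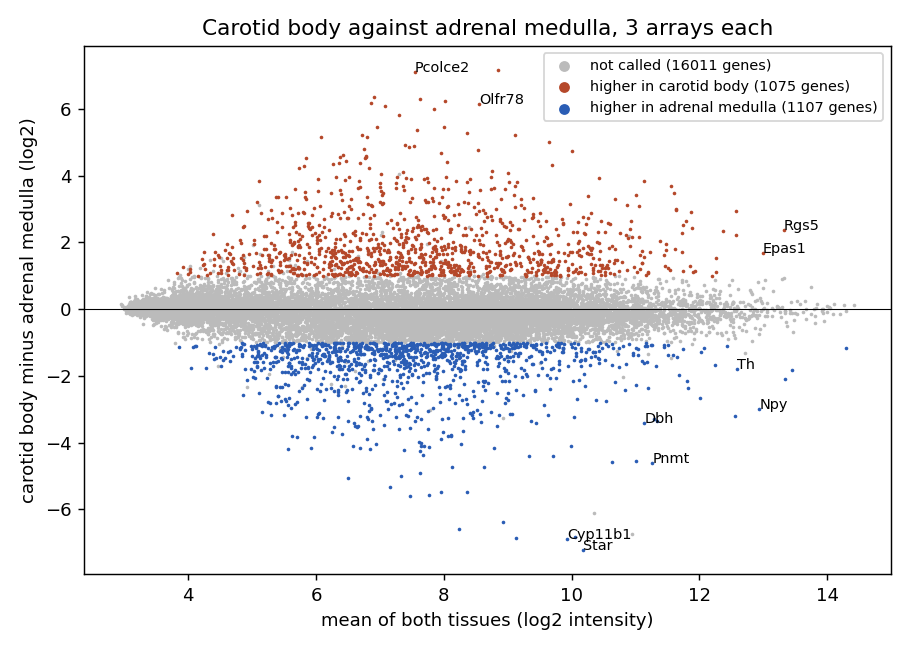
Each point is a gene; the horizontal axis is the mean of both tissues (log2 intensity) and the vertical axis the difference, carotid body minus adrenal medulla (log2), with 3 arrays per tissue. Coloured points passed the adjusted p and the 2-fold minimum, 1075 above and 1107 below the line at 0.

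The 10 genes with the largest differences toward carotid body under the naming rule were Methig1, Pcolce2, Meox2, Ccn3, Sfrp2, Scara3, Olfr78, Coch, Ly6h and Vit. Pcolce2, an enhancer of procollagen processing, had a log2 level of 11.10 ± 0.27 in carotid body and 3.99 ± 0.44 in adrenal medulla (SD, n = 3), a difference of 7.11 ± 0.24 (SE; adjusted p = 7.7e-06). The mesodermal transcription factor Meox2 differed by 6.37 and the secreted Wnt modulator Sfrp2 by 6.24. Toward adrenal medulla, the 10 largest were Star, Cyp11b1, Hao2, Cyp11a1, Agtr2, Mgarp, Olfm3, Prss35, Mc2r and Klhdc8a. Prss35 differed by -5.56 ± 0.21 (SE; adjusted p = 1.26e-05) and Agtr2, an angiotensin receptor, by -6.59 ± 0.74 (adjusted p = 0.000876). Star, Cyp11b1, Cyp11a1 and Mc2r are genes of steroid-producing cortex cells, and their levels in carotid body array 1 stood apart, as given with the cortex genes. Hao2, Agtr2, Mgarp, Olfm3 and Klhdc8a were also highest in array 1 among the carotid body arrays; without it their differences were -8.84, -7.51, -7.38, -6.60 and -6.28. Without carotid body array 3 those of Agtr2 and Hao2 were both -5.94, and without array 2 that of Hao2 was -5.83.

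Several genes of catecholamine synthesis were lower in carotid body. Of 16 measured members of that list, 6 were higher in adrenal medulla, 0 were higher in carotid body and 10 were not called. Tyrosine hydroxylase, Th, the rate-limiting enzyme, fell by 1.81 ± 0.24 (log2, SE; adjusted p = 0.00191) from 13.50 ± 0.46 in adrenal medulla to 11.69 ± 0.24 in carotid body (SD, n = 3). Dbh, which makes noradrenaline, differed by -3.41 ± 0.59 (adjusted p = 0.00548). Pnmt, which turns noradrenaline into adrenaline, differed by -4.62 ± 0.82 (adjusted p = 0.00607), and its 3 probe sets ranged from -7.35 to -0.71. Pnmt was 11.13 in carotid body array 1 and 7.65 and 8.08 in the other carotid body arrays; without array 1 the difference was -5.70, and without array 2 it was -3.97. Dbh was 7.86 in carotid body array 3 and 10.20 and 10.23 in arrays 1 and 2; without array 3 the difference was -2.63. The vesicular transporter Slc18a1 differed by -2.42 (adjusted p = 0.000287), and its 3 probe sets, 1 of them called, ranged from -2.42 to 0.01. Slc18a2 differed by -0.67 (adjusted p = 0.109; 0.0126 with the cohort as a block). Aromatic amino acid decarboxylase, Ddc, differed in the other direction, by 0.81 ± 0.19 (adjusted p = 0.0207), under 2-fold; its other probe set gave -0.40, and leaving out single arrays raised its adjusted p to as much as 0.0728. The camera test put the list lower in carotid body (adjusted p = 0.00125; adjusted p = 0.481 with an estimated correlation). In the same pools 14 of 15 fibroblast and matrix markers were higher; whether such a difference in composition lowers the catecholamine genes was not tested.

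**Figure D2:**
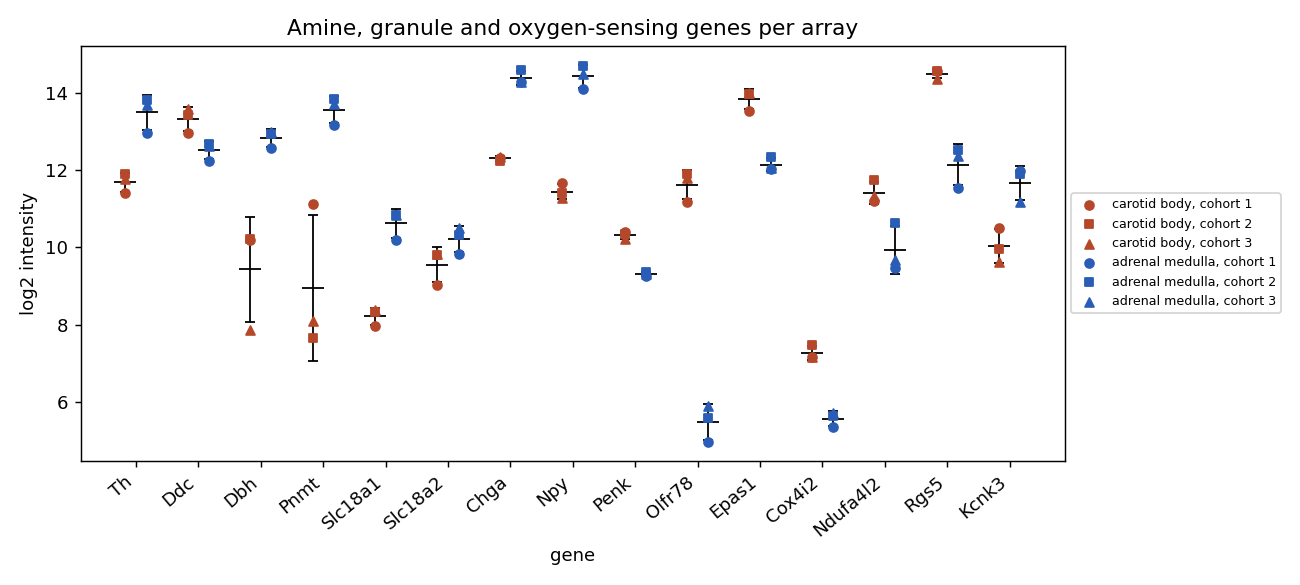
Log2 intensity of 15 catecholamine, granule and oxygen-sensing genes on each array; red is carotid body, blue is adrenal medulla, symbols mark the cohort, and bars show the mean and SD of 3 arrays. Th is higher in each adrenal medulla array, and Olfr78, Epas1 and Rgs5 are higher in each carotid body array.

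Among 32 genes of dense-core granules and exocytosis, 8 were higher in adrenal medulla and 1 was higher in carotid body. Chromogranin A, Chga, differed by -2.08 ± 0.13 (SE; adjusted p = 6.85e-05) and the prohormone convertase Pcsk1 by -4.23 ± 0.23 (adjusted p = 3.92e-05). The member higher in carotid body was Cplx1, a complexin of synaptic vesicle fusion, at 2.58 ± 0.28 (adjusted p = 0.000739). Camera gave an adjusted p of 0.0168 for this list and 0.69 with an estimated correlation, and 0.0716 without carotid body array 1; without adrenal medulla array 2 or 3, 5 members were higher in adrenal medulla, and without array 2 another was higher in carotid body. Of 28 neuropeptide genes, 5 were higher in adrenal medulla and 3 in carotid body. Npy differed by -2.99 and Gal by -3.29, while Penk, the enkephalin precursor, differed by 1.01 ± 0.11 (adjusted p = 0.000733). Of 17 measured sympathoadrenal transcription factors, 6 were higher in adrenal medulla and 2 in carotid body. Gata3 differed by -4.73 and Tfap2b by -4.04, against 1.93 for Lmo4. Neither of these lists was called (adjusted p = 0.835 and 0.708). Whether the composition of the pools, as given with the catecholamine genes, accounts for the differences in granule, neuropeptide and transcription factor genes was not tested.

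Of 16 measured candidates for oxygen sensing in glomus cells, the sensory cells of the carotid body, 6 were higher in carotid body and 3 in adrenal medulla. Olfr78, a lactate-responsive olfactory receptor, was at 11.63 ± 0.39 in carotid body and 5.48 ± 0.47 in adrenal medulla (SD, n = 3), a difference of 6.15 ± 0.28 (SE; adjusted p = 1.99e-05); its 4 probe sets ranged from 0.30 to 6.15. Rgs4 and Rgs5, regulators of G protein signalling, differed by 2.87 and 2.36. The hypoxia-inducible factor Epas1 differed by 1.69 ± 0.16 (adjusted p = 0.000464), from 12.14 to 13.84. The mitochondrial subunit genes Cox4i2 and Ndufa4l2 differed by 1.71 (adjusted p = 0.000299) and 1.49 (adjusted p = 0.011). Potassium channel genes Kcnma1 and Kcnk3 were lower in carotid body, by -2.14 and -1.64. The 5 probe sets of Kcnma1, 3 of them called lower in carotid body, ranged from -2.25 to 0.475. As a list the candidates were not called by camera (adjusted p = 0.0853). It gave 0.0353 with median-centred arrays and 0.0351 without adrenal medulla array 2. Fry, which does not set a list against the other genes, gave an adjusted p of 0.00586. In the same pools 13 of 16 smooth muscle and pericyte markers were higher; whether a difference in composition accounts for the candidates was not tested.

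Hif1a differed by 0.15 ± 0.14 (SE; adjusted p = 0.519). In the HIF pathway list 1 of 14 members was called, Epas1, and the list was not (adjusted p = 0.58). Among 22 HIF target genes, 3 were higher in carotid body, Ndrg1 at 1.55, Ldha at 1.26 and Adm at 1.24, and 0 were higher in adrenal medulla; the list was not called (adjusted p = 0.835). Subunits and assembly factors of oxidative phosphorylation shifted by a small amount toward adrenal medulla, with a median difference of -0.22 over 89 genes (camera adjusted p = 0.00177; adjusted p = 0.69 with an estimated correlation; 0.0508 without adrenal medulla array 1). At an adjusted p under 0.05 alone, 19 were lower in carotid body and 2 higher. The 2 higher, both past 2-fold, were Ndufa4l2 and Cox6b2, and the only member called lower was the assembly factor Ndufaf1, at -1.01. Those called lower were 3 and 2 without carotid body array 1 and 3, and 0 without carotid body array 2 or adrenal medulla array 1 or 2. Whether the composition or RNA quality of the pools accounts for the shift was not tested.

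Ion channel and receptor genes went both ways. Of 80 genes with potassium channel symbols, 14 were higher in carotid body, the noncoding Kcnq1ot1 among them, and 9 in adrenal medulla (adjusted p = 0.201 for the list). Kcna1 and Kcna2, voltage-gated channels of axons, differed by 4.13 ± 0.14 (SE; adjusted p = 7.7e-06) and 3.28, while the background channels Kcnk2 and Kcnk1 differed by -4.73 (-5.57 without carotid body array 1) and -3.57. The 4 probe sets of Kcna1 ranged from 0.12 to 4.58, and the 4 of Kcna2 from 0.007 to 3.28. Of 35 voltage-gated calcium and sodium channel genes, 3 were higher in carotid body, with Scn7a at 2.55, and 4 in adrenal medulla (adjusted p = 0.974). TRP and acid-sensing channels had 1 of 25 higher in carotid body, Trpm3 at 1.63, and 2 in adrenal medulla, with Asic4 at -2.64 (adjusted p = 0.835); without carotid body array 3 or adrenal medulla array 3 these were 3 and 1, and without adrenal medulla array 2 those in adrenal medulla were 1. The 6 probe sets of Trpm3, 1 of them called, ranged from -0.11 to 1.63. Among 50 ligand-gated receptor channel genes, 3 were called in each direction, Gria3 at -2.72 and Gabrb1 at 1.54 among them (adjusted p = 0.974); without adrenal medulla array 1, 5 were higher in adrenal medulla. P2ry12, an ADP receptor, led 2 of 34 aminergic, purinergic and cholinergic receptor genes higher in carotid body, at 3.60, against 1 higher in adrenal medulla (adjusted p = 0.11; 0.0449 without carotid body array 3; 4 higher in carotid body without adrenal medulla array 1). Of 21 genes with symbols of G protein signalling regulators, 5 were higher in carotid body, the binding protein gene Rgs7bp among them, and 3 in adrenal medulla (adjusted p = 0.128), with Rgs2 at -2.30. Of 39 olfactory receptor genes 2 were called, both higher in carotid body: Olfr78, and Olfr558 at 1.71 (adjusted p = 0.0162), whose adjusted p was 0.0628 and 0.0609 without adrenal medulla array 2 and 3. The list had an adjusted p of 0.048, 0.69 with an estimated correlation, 0.444 after quantile normalization, 0.122 with median-centred arrays, and 0.0614 to 0.136 without carotid body array 1 or 2 or adrenal medulla array 2 or 3. Tph1, of serotonin synthesis, differed by 2.48 and the serotonin transporter Slc6a4 by -1.81, the called members among 10 acetylcholine, GABA and serotonin genes (adjusted p = 0.806). Among 11 gasotransmitter genes, the haem oxygenase gene Hmox1 differed by -3.79 and Gucy1a2 by 1.16 (adjusted p = 0.974). Without carotid body array 1, 2 were higher in adrenal medulla, and without adrenal medulla array 1, 0 were higher in carotid body.

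Markers of connective tissue, vessel wall and glia were higher in carotid body. In the fibroblast and extracellular matrix list 14 of 15 members were higher and 0 lower, with a median difference of 2.93; Mfap5 differed by 5.47, Col1a1 by 3.30 and Lum by 3.30 (camera adjusted p = 2e-14; adjusted p = 0.0297 with an estimated correlation). Smooth muscle and pericyte markers had 13 of 16 higher, median 1.67, with Myh11 at 3.85 and Acta2 at 3.84 (adjusted p = 8.53e-11; 0.0553 with an estimated correlation). Among Schwann, satellite and type II glia markers, 10 of 14 were higher, median 1.83, with Mbp at 3.39 and S100b among them (adjusted p = 1.19e-09; 0.0982 with an estimated correlation). Endothelial markers had 5 of 18 higher, median 0.79, with Cldn5 at 3.97 and Cdh5 at 1.28 (adjusted p = 1.05e-06; 0.235 with an estimated correlation). Macrophage and lymphocyte markers had 2 of 20 higher, Mrc1 at 1.66 and Csf1r at 1.48 (adjusted p = 0.00177; 0.619 with an estimated correlation). In the ganglion neuron list 2 of 19 were higher, with Gap43 at 5.27 ± 0.23 (SE; adjusted p = 1.94e-05), and Rbfox3 was lower at -2.85; the list was not called (adjusted p = 0.11; 0.0451 without carotid body array 3, when 4 members were higher in carotid body; 1 was higher without any other single array).

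**Figure D3:**
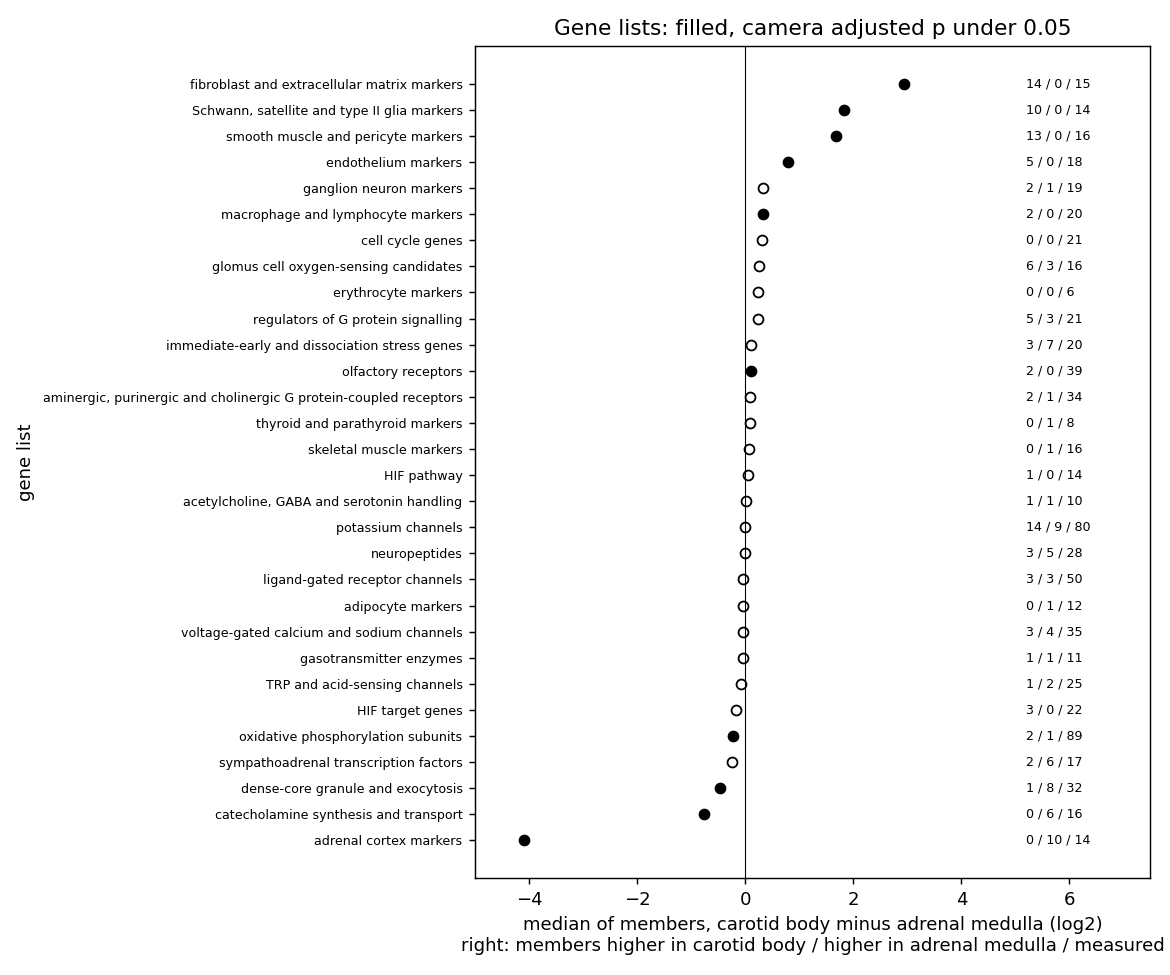
Median difference of each fixed list, carotid body minus adrenal medulla (log2), with filled points for a camera adjusted p under 0.05 at the preset correlation; numbers at the right are members higher in carotid body, higher in adrenal medulla and measured. Fibroblast and matrix markers lie farthest to the right, at 2.93, and adrenal cortex markers farthest to the left, at -4.10.

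Steroid-producing cortex genes were abundant in every adrenal medulla array and in carotid body array 1. The adrenal medulla pools therefore held cortex RNA, and a gene higher in them need not be a gene of the medulla. Of 14 measured cortex markers 10 were higher in adrenal medulla and 0 in carotid body, with a median of -4.10 (camera adjusted p = 0.000266; adjusted p = 0.618 with an estimated correlation). Star, the cholesterol carrier of steroid synthesis, was 12.06 in carotid body array 1, 3.85 and 3.81 in arrays 2 and 3, and 13.80 ± 0.24 in adrenal medulla (SD, n = 3). Its difference was -7.23 ± 2.00 (SE; adjusted p = 0.0357), and without carotid body arrays 1, 2 and 3 in turn it was -9.97 (adjusted p = 6.14e-06), -5.86 and -5.84. For Cyp11b1 the values were -6.88 (adjusted p = 0.0182) with all arrays and -9.06, -5.92 and -5.67 without those arrays in turn; its adjusted p was 0.0535 to 0.0707 without carotid body array 2 or any 1 of the adrenal medulla arrays. That of Mc2r was 0.0508 without adrenal medulla array 2. Without any other single array the adjusted p of Star was above 0.05, at most 0.122, and with an intensity trend and robust variances it was 0.138. Under that variance setting Cyp11b1, Hao2, Cyp11a1 and Mc2r had adjusted p of 0.0924, 0.0713, 0.0698 and 0.0654. Without carotid body array 2 and without each of adrenal medulla arrays 1, 2 and 3, the cortex markers called were 5, 6, 4 and 6.

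Other cell type lists were not called by camera. Among them, fry put only the erythrocyte markers under 0.05 (adjusted p = 0.0166). Of 16 skeletal muscle markers 1 was lower in carotid body, Myl1 at -1.83 (adjusted p = 0.58 for the list). Of 12 adipocyte markers 1 was lower, Lipe at -1.18 (adjusted p = 0.974). Of 6 erythrocyte markers 0 passed 2-fold, with Hbb-b2 at 0.79 (adjusted p = 0.109); 1 was higher in carotid body without carotid body array 3 or adrenal medulla array 2. Of 8 thyroid and parathyroid markers 1 was lower, Slc26a4 at -1.48 (adjusted p = 0.576). Immediate-early and stress genes had 3 of 20 higher in carotid body, with Egr3 at 2.28, and 7 higher in adrenal medulla, with Nr4a1 at -1.67 (adjusted p = 0.806). Without carotid body arrays 2 and 3 in turn and without adrenal medulla array 2, those higher in adrenal medulla numbered 3, 3 and 4. None of 21 cell cycle genes was called by limma, and 0 had an unadjusted p under 0.05 (adjusted p = 0.13 for the list; 0.0348 with the cohort as a block, 0.0158 without carotid body array 1 and 0.911, in the other direction, without array 3). The list's median lay 1.66 above the other carotid body arrays in array 3.

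**Figure D4:**
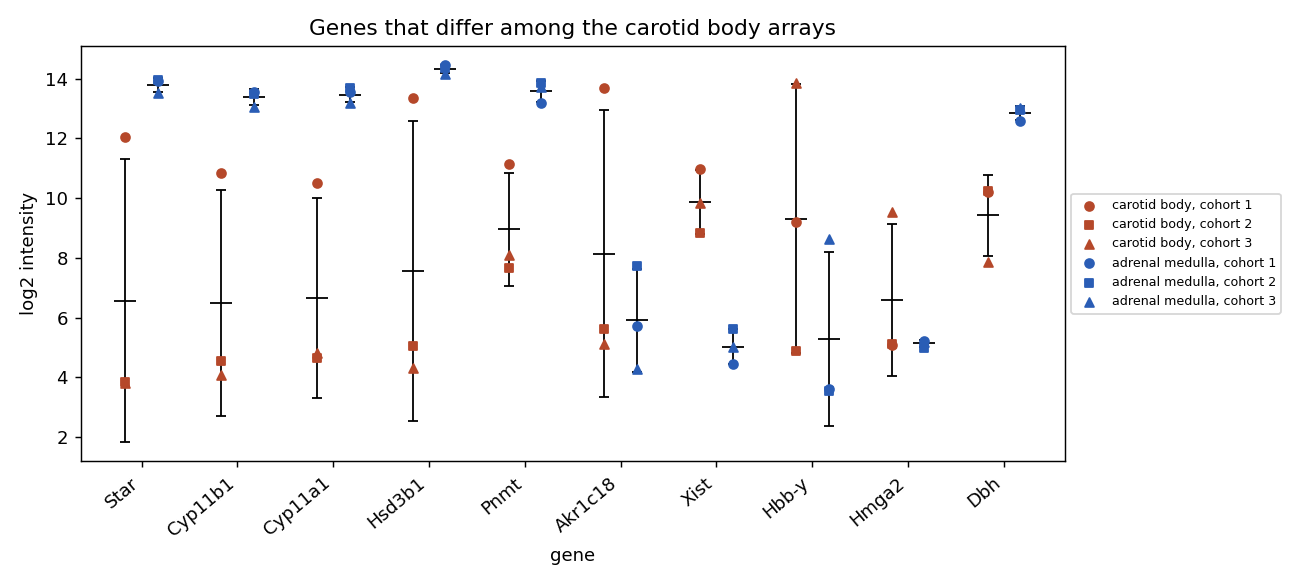
Log2 intensity on each array of 10 genes chosen after their values were seen; red is carotid body, blue is adrenal medulla, symbols mark the cohort, and bars show the mean and SD of 3 arrays. Star is 12.06 in carotid body array 1 and under 4 in arrays 2 and 3, and Hbb-y is 13.86 in carotid body array 3.

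Adjusted over the list alone, counts were equal to those above in 28 lists and differed in 2. The oxygen-sensing candidates had 4 rather than 3 members higher in adrenal medulla, and the cortex markers 12 rather than 10. With an estimated correlation, 1 of the 10 called lists held, the fibroblast and matrix markers. Besides the oxygen-sensing candidates and erythrocyte markers, fry put further lists that camera did not call under an adjusted p of 0.05. These were regulators of G protein signalling (0.0132), potassium channels (0.0417) and gasotransmitter enzymes (0.0417). For the olfactory receptors, called by camera, fry gave 0.0792. In 8 lists, 0 of them called, the median, the mean and the direction of camera did not share a sign: HIF targets, TRP and acid-sensing channels, neuropeptides, gasotransmitter enzymes, skeletal muscle, adipocyte, thyroid and immediate-early genes.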

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

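Leaving out carotid body arrays 1 and 3 together was chosen after seeing the data; the estimated correlation was fixed beforehand as part of the list test. A choice of pseudocount was not run, since the values are log2. Of 540 list results under the alternatives, 467 kept their direction and their side of the threshold, as did 1953 of 2149 values of named genes. Of the 10 called lists, 7 stayed called in every alternative but the estimated correlation, with a highest adjusted p of 0.0205; the others were granule, oxidative phosphorylation and olfactory receptor genes. With the cohort as a replicate block, 2737 and 2108 probe sets and 1099 and 1132 genes were called higher in carotid body and adrenal medulla, and 2180 of the 2182 genes called without it were shared. With the block the adjusted p fell under 0.05 for the cell cycle list (0.0348) and Slc18a2 (0.0126) and rose above it for Hif3a (0.0513) and Ntrk2 (0.0535), these genes staying under 2-fold, and crossed it for no other list or named gene. Leaving out arrays or cohorts gave 1626 to 3025 and 952 to 2499 probe sets higher in carotid body and adrenal medulla and 532 to 1269 genes higher in adrenal medulla; the lowest counts came without cohort 2, where 1294 of 1339 called genes were among the 2182, while 2344 and 2213 genes were called without cohorts 1 and 3, which leave as many arrays. Limma's treat tests against 1.5-fold rather than against no difference, and was used without the 2-fold minimum. It called 1659 and 1013 probe sets and 787 and 569 genes. Without carotid body arrays 1 and 3, 1934 of the 2182 genes were called in the same direction and 0 in the opposite one; the lone carotid body array is there assumed to vary like the adrenal arrays. Of 123 named genes with an adjusted p under 0.05, 75 passed without each array and cohort and in every processing alternative that tested them. Without each single array 102 passed, and 46 were lost without cohort 2. Treat was not run for the named genes. With the dimmer probe sets removed, 117 of all 127 named genes were tested, and those not tested there were counted as not lost. For all changes below the cause was not tested.

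An estimated correlation gave adjusted p of 0.481 for catecholamine, 0.69 for granule, oxidative phosphorylation and olfactory receptor, 0.618 for cortex, 0.235 for endothelium, 0.0553 for smooth muscle, 0.0982 for glia and 0.619 for macrophage lists. Over the runs that left out arrays or cohorts, adjusted p ranged from 0.00131 to 0.0716 for granule genes, 0.0312 to 0.152 for oxygen-sensing candidates, 2.61e-05 to 0.0508 for oxidative phosphorylation, 0.00493 to 0.259 for olfactory receptors, 0.0449 to 0.264 for aminergic receptors, 0.02 to 0.314 for ganglion markers and 0.0158 to 0.911 for cell cycle genes. The cell cycle direction reversed without carotid body array 3. Lists that were not called and reversed in at least 1 of these runs had, over all of them, adjusted p of 0.587 to 0.997 for HIF targets, 0.662 to 0.946 for calcium and sodium channels, 0.732 to 0.985 for ligand-gated channels, 0.89 to 0.985 for gasotransmitter enzymes, 0.246 to 0.928 for adipocyte markers and 0.374 to 0.921 for immediate-early genes. Median-centred arrays gave 0.0524 for granule genes, 0.0353 for oxygen-sensing candidates and 0.122 for olfactory receptors, and reversed calcium and sodium channels (0.969) and adipocyte markers (0.886). Quantile normalization gave 0.444 for olfactory receptors and reversed neuropeptides (0.971). Without the dimmer probe sets, granule genes had 0.0531 and oxidative phosphorylation 0.0509, and reversals were neuropeptides (0.936), acetylcholine, GABA and serotonin handling (0.636), skeletal muscle (0.346), adipocyte (0.936) and thyroid markers (0.346). With the mean of all probe sets, oxygen-sensing candidates had 0.0351, and ligand-gated channels (0.981) and gasotransmitter enzymes (0.895) reversed. Array weights reversed ligand-gated channels (0.926) and adipocyte markers (0.909), and the block reversed adipocyte markers (0.873). Without carotid body arrays 1 and 3, granule genes had 0.24, aminergic receptors 0.0205 and ganglion markers 0.0115, and reversals were HIF targets (0.967), calcium and sodium channels (0.881), ligand-gated channels (0.697), gasotransmitter enzymes (0.965) and immediate-early genes (0.82). Named genes that reversed were Pcna (-0.0232 with median centring, -0.178 to 0.293 over left-out arrays), Mcm2 (-0.734 to 0.0392 over left-out arrays), Ntrk2 (-0.00605 with the mean of probe sets) and Hif1a (-0.0796 without carotid body arrays 1 and 3). Counts of list members moved by over 1.5 times in 108 of 1020 cases. Signal near the floor limits dim genes, for which no detection call was given.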

Other observations

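The tests on carotid body array 1, on cell division and blood in array 3, and on Xist were chosen after their values were seen; those on other splits of the arrays, fetal genes, Hox genes and mast cell genes were set before their values were seen. Splitting the 6 arrays into 3 and 3 can be done in 10 ways; the real split called 4744 probe sets, the highest of the others called 0, and 1 of the 10, the real one, reached that count. Of the others, 3 part all 3 cohort pairs as the real one does and 6 do not. With 10 splits the share cannot fall under 0.05. Every other split mixes the tissues within both groups, so the tissue difference enters the spread and few calls are possible. The count of 0 there therefore decides nothing.

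Of 33 measured Hox genes, 2 were higher in carotid body, Hoxa2 by 1.80 ± 0.14 (log2, SE; adjusted p = 0.000191, limma) and Hoxa3 by 1.42, and 8 were higher in adrenal medulla, with Hoxb9 at -4.25, Hoxc8 at -3.24, Hoxb6 at -3.16 and Hoxc4 at -2.88. Without carotid body array 1, Hoxb9, Hoxc8 and Hoxb6 were at -5.10, -3.98 and -3.89. Without carotid body array 2, Hoxc8 was at -2.35. It was not called without adrenal medulla array 1 or 2, nor Hoxb5 (-1.82) without any 1 of the adrenal medulla arrays. Dlx5 and Dlx6, chosen after their values were seen, were higher in carotid body by 3.84 ± 0.13 (adjusted p = 7.7e-06) and 3.30. A hypothesis that paralogue number follows the position of the organs was tested over the 31 Hox genes other than Hoxa3 and Hoxb9, which had been seen. The Spearman correlation of paralogue number and difference was 0.241 (100000 permutations, two-sided p = 0.192; across genes, which are not independent), opposite in sign to the prediction and in the range set beforehand against it. That range was ill chosen: 15 of the 31 genes lay under the median of all values in both tissues, where differences are compressed, so the test neither supports nor excludes the hypothesis. Mast cell proteases Cpa3 and Cma1 were higher in carotid body by 5.46 and 4.81, also chosen after their values were seen. The hypothesis that carotid body pools may hold more mast cells predicted most of the other mast cell genes called higher there; 4 of 12 were, which leaves it open. Of the 12, 2 reached the median of all values in adrenal medulla and 5 in carotid body. Mcpt4 (3.37), Fcer1a (2.25), Kit (1.42) and Tpsb2 (1.09) were higher in carotid body, and Slc45a3 (-1.71) was lower. Ms4a2 (0.95, adjusted p = 0.00362, limma) and Mrgprb1 (0.97, adjusted p = 0.0057) fell just short of 2-fold and were not called. The count of 4 thus rests on the 2-fold minimum.

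Carotid body array 1 carried adrenal transcripts. In it 22 genes stood at least 4 (log2) above the mean of the other carotid body arrays, against 0 in array 2 and 3 in array 3, and the cortex list had a median 3.67 above them. Carry-over from the adrenal medulla pools of this series is argued against as the whole cause, since 10 of the 22 genes (45.5%) lay over 1 above the highest adrenal medulla array; Akr1c18, a steroid dehydrogenase, was 13.68 there and at most 7.72 in adrenal medulla. A swapped adrenal label is argued against by Olfr78, 5.29 above the highest adrenal medulla array. A candidate source is RNA of another adrenal that includes female tissue: Pnmt stood 3.26 and Xist 1.63 above the other carotid body arrays, although Xist also differed by 0.98 between those. These values prompted that candidate, so they are no test of it. An explanation other than foreign RNA or a swapped label was not tested.

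Carotid body array 3 carried embryonic globin transcripts. Hbb-y, a globin of yolk sac red cells, stood 6.83 above the mean of the other carotid body arrays, at 13.86 against 9.19 and 4.88, with 8.64 in adrenal medulla array 3; Hbb-bh1, Hba-x, Hmga2 and Sox11 were 8.78, 8.02, 9.52 and 7.92 in it and at most 5.35 in the other carotid body arrays, while Igf2bp3 was 7.21 against 7.13 and 7.42. More adult blood is not decided by the erythrocyte list, which stood at -0.16. Its median level of 4.38 in array 3 lies where differences are compressed. The members Alas2 and Hbb-b2 were not raised in array 3. Alas2 was 6.01 there against 6.24 and 6.71, and the tissue difference of Hbb-b2 was 0.79 with and without that array. RNA of embryonic or fetal tissue was predicted to raise most of the fetal list; 1 of 15 genes (6.67%), Afp, rose by over 1, in the range set beforehand against it, and Afp was also 7.01 in array 1. Of the 14 others, 6 reached the median of all values in carotid body and would hide a small share. In array 3 Mest, Igf2, Igf2bp1, Peg3 and Mdk stood 0.82, 0.51, 0.27, 0.26 and 0.24 above the mean of the other carotid body arrays. Epor stood at -0.29, and these shifts were not tested. The 8 under the median, where differences are compressed, moved by -0.28 to 0.27. A large share has no support here. A small one stays open, without support from the raised genes that prompted it. Cell division among adult cells was predicted to raise the cell cycle list and to leave Hbb-y raised by at most 1. The list stood 1.66 higher, but Hbb-y rose by 6.83, against that prediction. Hbb-y is part of the pattern and had been seen when the prediction was written. The test therefore decides nothing, and cell division stays open too.

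Xist, the transcript of the inactive X chromosome, was 10.96, 8.84 and 9.82 in the carotid body arrays and 4.45, 5.60 and 5.02 in adrenal medulla, a difference of 4.85 ± 0.52 (SE; adjusted p = 0.000693, limma), although the cohorts are stated to be the same animals. Foreign RNA in carotid body arrays 1 and 3 alone is argued against by array 2, where Xist lay 3.23 above the highest adrenal medulla array. RNA of female mice in the carotid body pools may account for it: the 3 measured Y-linked genes had a median difference of -0.77, and their mean was lower in carotid body in all 3 cohorts, by -0.82, -0.89 and -0.60. Among the carotid body arrays their order was not the reverse of that of Xist, and a tissue difference in Y-linked genes cannot be told apart from it with these arrays, so it stays open beside an untested difference between the tissues.

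Adipoq, an adipocyte hormone chosen after its values were seen, was 10.02, 8.84 and 7.40 in carotid body and 9.24, 7.41 and 4.06 in adrenal medulla of cohorts 1, 2 and 3. The neuronal genes Slc6a2, Prph and Htr3a, likewise chosen, were 8.85, 7.55 and 6.35 in carotid body array 3 and 11.60, 9.69 and 9.32 in array 2. Of 17 liver genes, 4 were raised by over 1 in carotid body array 1 over the mean of the others. These were Kng1 by 3.58, Serpina1b by 2.96, Hamp by 2.71 and Hp by 1.05. Kng1, Serpina1b and Hamp were 7.05, 7.25 and 6.47 in array 1 and at most 3.83, 4.00 and 4.25 in adrenal medulla. The median of the 17 was 0.14 above the mean of the others. The source of these transcripts was not tested.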
